A study of Mus musculus with 6 samples.

How the data were processed

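Single-cell RNA, B cell receptor and hashtag data were collected from draining lymph nodes of 3 wild-type (WT) and 3 Pik3cg knockout (KO) mice at day 34, after 3 immunizations with NP-Ova in alum, a hapten-coupled ovalbumin. Per the labels' protocols, cells were depleted of non-B cells and of IgD-bearing cells. This enriched part made up 70% of the mixture and untouched cells the other 30%. Each mouse received its own antibody hashtag, and the pool was run on 2 identical droplet lanes with a kit that captures both the transcriptome and receptor transcripts. The hashtag table names the mouse of a barcode, so the mouse was the replicate (n = 3 per genotype), and the lanes were technical repeats of the same pool and were summed.

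The deposited gene expression values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, made with Cell Ranger 7.0.1 per the file headers and aligned to mm10 per the submitters' processing notes. The deposited receptor files hold assembled contigs with their gene calls as text and UMI counts per contig, also raw. The hashtag table holds the authors' own calls in text form, and the rule behind those calls is not given in the sources used here. No value was normalized before deposit. Gene positions and receptor V segments came from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names.

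Of 23516 barcodes, 19270 (81.9%) carried a single hashtag, 3902 (16.6%) several and 344 none. Barcodes with a single hashtag were kept if they had at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs, which removed 62. Scrublet, as implemented in scanpy, was then run per lane. Its automatic threshold called 0 cells in lane 1, so the threshold of lane 2 (a score of 0.301) was applied to both lanes. It removed 227 cells (1.18%), and it marked 20.2% of the barcodes with several hashtags. The remaining 18981 cells were scaled to 10000 counts, log-transformed and clustered on 2000 variable genes without immunoglobulin and T cell receptor genes (30 principal components, 15 nearest neighbours, Leiden resolution 1), giving 28 clusters. Clusters were named by lists of marker genes, and 5 clusters with 1140 cells stayed unnamed. The marker lists were fixed before the data were examined, as were the gene lists, the tests and the naming of genes; the scoring rule was set afterwards (at least 3 markers detected in at least 10% of a cluster's cells, and no other list with more members among its 10 leading genes). B-lineage cells were clusters with Cd79a in at least 30% of cells and Cd3e in under 30%.

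UMI counts were summed per mouse and class, with at least 10 cells per mouse required, and fitted with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, two-sided, Benjamini-Hochberg adjusted p under 0.05). Standard errors (SE) were taken as the absolute log2 fold change over the square root of F. All log2 fold changes are KO relative to WT, and CPM values use TMM library sizes. The class of antibody-secreting cell-like cells was not tested, because 4 of the 6 mice had fewer than 10 cells, and no cluster met the rule for memory B-like cells. An unnamed B-lineage cluster, cluster 9, was compared by its number, a choice made after seeing the data. Gene lists were tested with camera of limma 3.58.1 on the edgeR fit (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists of a class), with an estimated correlation and with fry. Lists with fewer than 3 tested members were left out, among them that of the PI3K gamma complex in every class and sex-linked genes. The lists covered PI3K subunits, FOXO, mTORC1 and MYC targets, metabolism, secretion, B cell, germinal centre and plasma cell programmes, cell cycle, activation, dissociation and stress, interferon, antigen presentation, migration, memory, immunoglobulin constant genes, T cell programmes and ribosomal proteins. Differences of the genotype effect between classes were tested as an interaction with the mouse as a block. Those pairs of classes were chosen after seeing that antibody-secreting cells were too few for the pairs first intended.

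The genes named were Pik3cg, then per class the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 20 CPM in a genotype and no overlap between the mice of the 2 genotypes, without receptor V, D and J segments and predicted genes. Up to 4 members of each list past the threshold were added, and the 6 genes with the smallest p where fewer than 6 qualified. Genes outside that rule are marked where they appear.

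Shares of cells, isotypes and clones per mouse were compared with a two-sided exact permutation test over the 20 assignments of 6 mice, in which the smallest possible p is 0.1. Receptors were taken from productive contigs, 3674 heavy and 14432 light among 18106. A clone was the same mouse, V gene, J gene and CDR3 nucleotide sequence, and expansion was measured at equal numbers of cells per mouse over 500 draws. The nucleotide difference of V segments from the reference was added after seeing the data, with V segments above 20% difference left out (6 of 2693 cells). Intervals and limits from counts of 0 (3 counts) cover counting error only.

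The edgeR script was tested on simulated counts with 200 changed genes per class, drawn with the trended dispersion alone, without gene-specific spread or an outlying mouse. It recovered 74.2% of 2-fold and 99.0% of 4-fold changes in germinal centre B-like cells, 85% and 98.9% in follicular B-like cells, 77.5% and 97.8% in T-like cells, and 76.1% and 100% in cluster 9, with 10, 5, 8 and 5 false calls. A raised list was found in germinal centre B-like, follicular B-like and T-like cells but not in cluster 9 (camera adjusted p = 0.196). Camera also called 1 of 25, 2 of 25, 1 of 26 and 2 of 21 lists that had not been raised, in the same order.

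Alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, each lane alone, immunoglobulin genes left out, Scrublet calls kept, a mitochondrial limit of 5%, Leiden resolution 2, other clone and contig rules, and each mouse left out. Leaving out clusters that looked damaged or were led by interferon-stimulated genes was added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.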

Results

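Gene expression, B cell receptor sequences and hashtags were measured in single cells of the draining lymph node of 3 WT mice (WT1 to WT3) and 3 Pik3cg KO mice (KO1 to KO3). The nodes were taken at day 34, after 3 immunizations with the hapten-protein conjugate NP-Ova in alum. The retained cells numbered 3193, 2949 and 3549 in WT1, WT2 and WT3 and 2787, 4004 and 2499 in KO1, KO2 and KO3. Their total depth was 9481100, 6936134 and 8440967 UMIs in the WT mice and 8210776, 13505792 and 7685553 UMIs in the KO mice, with medians of 1972 to 2460 UMIs per cell. The cells were named from marker genes as follicular B-like (9483 cells), germinal centre B-like (4136), T-like (3544), dendritic cell-like (259), NK-like (188), macrophage or monocyte-like (106), plasmacytoid dendritic cell-like (74) and antibody-secreting cell-like (51). The title of the series poses the question of what PI3K gamma in B cells does for antibody responses and for the formation of antibody-secreting cells.

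Pik3cg (ENSMUSG00000020573, GRCm38 chromosome 12, 32173473 to 32208659, minus strand) encodes the catalytic subunit of PI3K gamma. Its RNA was still counted in the KO mice. In follicular B-like cells it reached 44.5 ± 2.86 CPM in WT and 36.9 ± 2.96 CPM in KO mice (SD, n = 3 each; log2 fold change -0.27, SE 0.11, edgeR adjusted p = 0.647). Every KO mouse lay below every WT mouse, a separation that chance gives in 10% of cases. The log2 fold change was -0.17 (SE 0.16, edgeR adjusted p = 1.000) in germinal centre B-like cells and 0.18 (SE 0.26, edgeR adjusted p = 0.926) in T-like cells. The antibody-secreting cell-like cells held 5, 2 and 2 Pik3cg UMIs in the WT mice and 0, 4 and 0 in the KO mice. The labels do not give the deleted part of the gene, so these transcript counts do not check the genotype.

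In follicular B-like, germinal centre B-like and T-like cells, genes around Pik3cg differed between the genotypes more often than genes elsewhere, which was predicted for follicular B-like cells before the result was seen. Within 20 Mb of Pik3cg, 16 of 67 tested genes (23.9%) had an unadjusted p under 0.05 in follicular B-like cells, against 6.84% of all other genes (odds ratio 4.27, one-sided Fisher's exact p = 9.98e-06). In germinal centre B-like cells the share was 15 of 71 (21.1%) against 5.10% (odds ratio 4.98, one-sided Fisher's exact p = 2.84e-06). In T-like cells it was 15 of 59 (25.4%) against 7.39% (odds ratio 4.27, one-sided Fisher's exact p = 2.07e-05). In cluster 9 it was 2 of 19 (10.5%) against 4.88% (odds ratio 2.29, one-sided Fisher's exact p = 0.240). Named genes of this region that passed the threshold over all genes were Nova1, a neuronal splicing regulator 14.49 Mb from Pik3cg, Rnf144a, an E3 ubiquitin ligase 5.76 Mb away, and Asap2, an Arf GTPase-activating protein 10.9 Mb away. The predicted gene Gm49692, chosen after its values were seen, lies 11.86 Mb away and passed with log2 fold changes of 5.85 in germinal centre B-like and 5.41 in follicular B-like cells. Over the alternatives the odds ratio ran from 2.77 to 9.10 in follicular B-like cells (highest one-sided Fisher's exact p = 0.00583) and from 3.61 to 9.24 in germinal centre B-like cells (highest one-sided Fisher's exact p = 0.000173). In T-like cells it ran from 0.572 with lane 1 alone (one-sided Fisher's exact p = 0.862) to 5.02, and it was 2.62 without KO2 (one-sided Fisher's exact p = 0.00285).

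**Figure D1:**
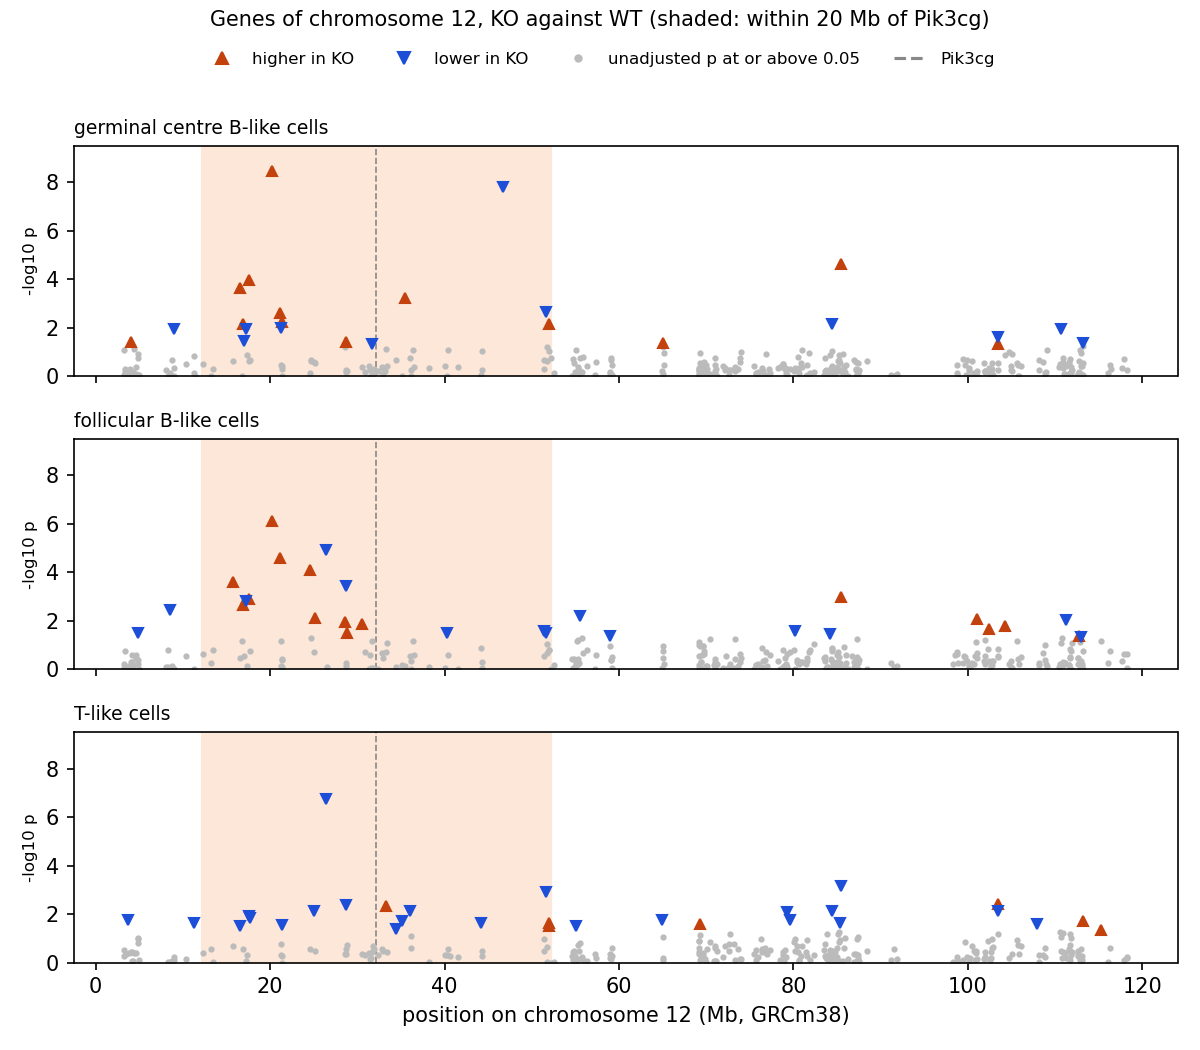
Unadjusted p (as -log10) of the tested genes along chromosome 12 in Mb, by class, with genes higher or lower in KO marked by triangles and the window of 20 Mb on each side of Pik3cg shaded. In follicular B-like cells 23.9% of the tested genes in the window had an unadjusted p under 0.05, against 6.84% of all other genes.

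The composition of the loaded mixture was compared first. T-like cells made up 24.8% ± 6.87 of WT and 12.6% ± 0.694 of KO cells (SD, n = 3 each), and B-lineage cells 67.8% ± 6.97 and 81.7% ± 0.505. For both, the mice of the genotypes did not overlap, which chance gives in 10% of cases (two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 mice can give; Benjamini-Hochberg p = 0.275 over 11 shares). An edgeR fit of cell numbers gave the T-like class a log2 fold change of -0.98 (SE 0.23, edgeR adjusted p = 0.0334 over 5 classes). Germinal centre B-like cells were 36.6%, 7.68% and 11.5% of B-lineage cells in WT1, WT2 and WT3 and 24.3%, 43.7% and 42.7% in KO1, KO2 and KO3. The means were 18.6% ± 15.7 and 36.9% ± 11.0, a difference of 18.3 points (exact permutation p = 0.2, Benjamini-Hochberg p = 0.314). The genotypes overlapped through WT1, and without it every KO mouse lay above both WT mice, with a difference of 27.3 points (exact permutation p = 0.2). Follicular B-like cells were 78.4% ± 15.8 of B-lineage cells in WT and 58.3% ± 11.96 in KO mice (exact permutation p = 0.2). Per the labels, these are shares of a mixture that was enriched for B cells without IgD and topped up with untouched cells. The mixing of each mouse is not recorded. The stated depletion is not plain in the retained cells. Follicular B-like cells made up 52.6% of WT and 47.7% of KO cells. IgD was the isotype of 1368 of the 2706 retained cells with a heavy chain.

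Antibody-secreting cell-like cells, the class in the series title, numbered 14, 6 and 5 in the WT mice and 4, 19 and 3 in the KO mice. They were 0.261% ± 0.157 of all WT and 0.246% ± 0.198 of all KO cells (SD, n = 3 each; exact permutation p = 0.9), and 0.379% ± 0.201 and 0.301% ± 0.241 of B-lineage cells (exact permutation p = 0.5). Relative to germinal centre and antibody-secreting cells together, they were 1.61%, 4.23% and 1.72% in the WT mice and 0.717%, 1.31% and 0.345% in the KO mice (exact permutation p = 0.1, Benjamini-Hochberg p = 0.275), without overlap between the genotypes (chance share 10%). This denominator was not among those fixed before the data were examined. It consists mostly of germinal centre B-like cells, which numbered 858, 136 and 286 in the WT mice and 554, 1436 and 866 in the KO mice. With these numbers no gene comparison was made in the class.

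**Figure D2:**
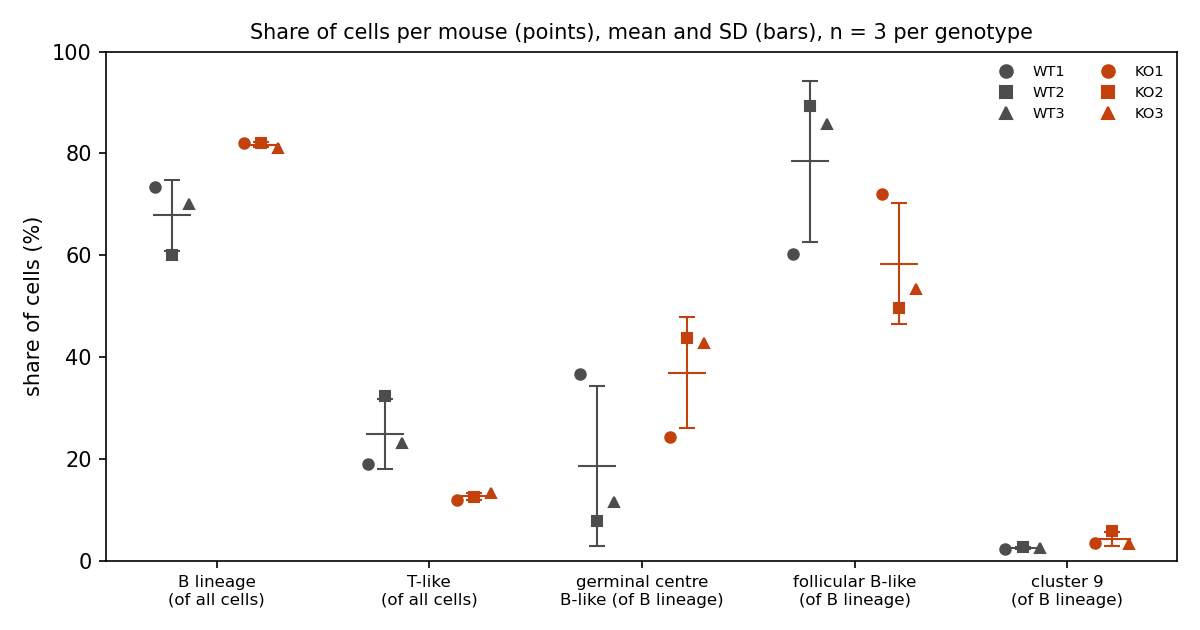
Shares in percent per mouse (points) for WT and KO, with the mean and SD. T-like cells ran from 19.0% to 32.4% of cells in WT and from 11.9% to 13.3% in KO mice.

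In germinal centre B-like cells, 11 of 10114 tested genes passed the threshold, 9 higher and 2 lower in KO (edgeR; 13 by DESeq2). Tanc2 (ENSMUSG00000053580, chromosome 11, 105589986 to 105929304), a synaptic scaffold protein, rose from 16.6 ± 2.72 to 37.1 ± 2.39 CPM (SD, n = 3 each; log2 fold change 1.26, SE 0.16, edgeR adjusted p = 0.00254). Eya1 (ENSMUSG00000025932, chromosome 1, 14168954 to 14310235), a transcriptional coactivator with phosphatase activity, rose from 32.3 ± 4.46 to 55.4 ± 1.87 CPM (log2 fold change 0.80, SE 0.11, edgeR adjusted p = 0.00393). Fos, an immediate-early gene of the AP-1 family, rose by a log2 fold change of 0.56 (SE 0.09, edgeR adjusted p = 0.0239). Ryr2, a calcium release channel, rose by 1.35 (SE 0.22, edgeR adjusted p = 0.0239). The fallers were Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156), an inducible chaperone of the Hsp70 family, from 23.2 ± 0.169 to 4.44 ± 2.78 CPM (log2 fold change -2.20, SE 0.30, edgeR adjusted p = 0.00393), and Nova1. Nova1 went from 15.3 ± 6.19 to 0.410 ± 0.502 CPM (log2 fold change -5.31, SE 0.48, edgeR adjusted p = 7.93e-05). Among the other genes called, all higher and chosen after their values were seen, were Cdk5rap1 and the light-chain V segments Igkv2-137, Igkv12-98 and Igkv6-17. V segment RNA depends on the clones sampled, and whether expanded clones carried these segments was not tested. Left-out mice moved the count to 3 without WT1, 6 without WT3 and 17 without KO1 or KO3. Each lane alone gave 5 and 4 genes, and a fit without immunoglobulin genes gave 19. Without the filter on low counts the count was 167.

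Of 26 gene lists tested in germinal centre B-like cells, 3 were higher in KO by camera and none was lower. In the interferon-stimulated list all 14 measured members were higher, with a median log2 fold change of 0.47 (camera adjusted p = 0.000733; adjusted p = 0.905 with an estimated correlation). Stat2 was the 1 member that passed when adjusted over the list alone (log2 fold change 0.59, SE 0.17). KO1 carried this list: without it the median was -0.12. In the cholesterol synthesis list 16 of 19 members were higher (median 0.18, camera adjusted p = 0.0125; adjusted p = 0.905 with an estimated correlation). In the MHC class II presentation list all 10 were (median 0.10, camera adjusted p = 0.0207; adjusted p = 0.905 with an estimated correlation). Adjusted over the list alone, 0 members of either passed by edgeR. The 23 lists without a call included those of the germinal centre (camera adjusted p = 0.166), light zone (0.402), dark zone (0.464), S phase (0.793), G2 and M phase (0.161), MYC targets (0.464), the antibody-secreting cell programme (0.182) and the unfolded protein response (0.114). The dissociation and stress list had no call either (camera adjusted p = 0.711), and its test and mean pointed down (mean -0.16) while its median was 0.08. Medians, means and tests also differed in sign for the PI3K, FOXO, mTORC1, glycolysis, B cell receptor activation, NF-kB, migration and immunoglobulin constant lists, none with a call.

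In follicular B-like cells, 6 of 9826 genes passed, 5 higher and 1 lower in KO (edgeR; 9 by DESeq2). Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), the IgG1 constant region, rose from 17.6 ± 6.95 to 52.4 ± 3.29 CPM (SD, n = 3 each; log2 fold change 1.52, SE 0.20, edgeR adjusted p = 0.0141). Over its alternatives this ran from 0.82 to 2.23 (adjusted p 2.41e-24 to 0.608). Parm1 (ENSMUSG00000034981, chromosome 5, 91517615 to 91626894), a member of the memory B list, rose from 0.922 ± 0.504 to 7.26 ± 1.48 CPM (log2 fold change 2.92, SE 0.40, edgeR adjusted p = 0.0207). Asap2 rose by a log2 fold change of 1.60 (SE 0.25, edgeR adjusted p = 0.0418, range over its alternatives 1.10 to 2.63, adjusted p 1.26e-05 to 0.729). Rnf144a (chromosome 12, 26300964 to 26415254) fell from 84.1 ± 5.08 to 56.1 ± 2.02 CPM (log2 fold change -0.58, SE 0.09, edgeR adjusted p = 0.0226). Below the threshold, Ighg2b had a log2 fold change of 1.71 (edgeR adjusted p = 0.0610) and Dusp2, a phosphatase of MAP kinases, -0.39 (edgeR adjusted p = 0.0708). The remaining calls, Gm49692 (edgeR adjusted p = 0.00748) and Gm26917, were chosen after their values were seen. Germinal centre B-like cells of WT and KO mice held Ighg1 at 755 and 810 CPM and Parm1 at 89.0 and 105 CPM. T-like cells, which do not make Ighg1, held it at means of 7.45 and 39.2 CPM (log2 fold change 2.35, SE 0.64, edgeR adjusted p = 0.217). The KO mean rests on KO1, with 98.2 CPM of Ighg1 against 12.7 and 6.61 CPM in KO2 and KO3. The count was 0 by edgeR without WT1, WT2 or KO3 (554, 574 and 699 genes at an unadjusted p under 0.05), 1 without WT3, 23 without KO1 and 13 without KO2. It was 7 with lane 1 alone, of which 1 was shared with these 6. It was 1 with lane 2 alone. It was also 1 with Scrublet calls kept, where a cluster of 4014 cells closest to the follicular list stayed unnamed and the class shrank from 1415 to 753 cells in WT1 and from 1632 to 853 in KO2. It was 2 at resolution 2, 18 without the clusters led by interferon-stimulated genes and 186 without the filter on low counts.

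Of 26 lists tested in follicular B-like cells, 9 were higher and 2 lower in KO by camera. With an estimated correlation or with fry 0 kept a call, against 12 lists at an unadjusted camera p under 0.05. Ribosomal protein genes were higher as a group: 84 of 88 had a positive log2 fold change (median 0.11). Of these genes, 57 passed when adjusted over the list alone (camera adjusted p = 3.02e-24; adjusted p = 0.430 with an estimated correlation). The immunoglobulin constant list had a call as higher (5 of 10 members higher, median 0.10, mean 0.52, camera adjusted p = 2.48e-05; adjusted p = 0.198 with an estimated correlation). It rested on Ighg1, Ighg2b and Igha, which were higher when adjusted over the list alone, with Igha at a log2 fold change of 1.00 (SE 0.29). The dissociation and stress list was lower (13 of 17 members, median -0.17, camera adjusted p = 5.16e-05; adjusted p = 0.414 with an estimated correlation). FOXO targets were lower as well (median -0.09, camera adjusted p = 0.00237; adjusted p = 0.430 with an estimated correlation). Adjusted over the list alone 3 of 17 passed: Tsc22d3, a glucocorticoid-induced regulator (log2 fold change -0.38, SE 0.08), Txnip, an inhibitor of thioredoxin (-0.30, SE 0.07), and Irs2, an insulin receptor substrate (-0.34, SE 0.10). Further lists had a call as higher. They were MYC targets and ribosome biogenesis (21 of 26 members higher, camera adjusted p = 0.000381; adjusted p = 0.532 with an estimated correlation), glycolysis (11 of 14 higher, camera adjusted p = 0.00667; adjusted p = 0.476 with an estimated correlation), nuclear genes of oxidative phosphorylation (24 of 27 higher, camera adjusted p = 0.0279; adjusted p = 0.532 with an estimated correlation) and mitochondrially encoded genes (all 11 higher, camera adjusted p = 0.000246; adjusted p = 0.430 with an estimated correlation). Adjusted over the list alone, 0 members of the latter 3 lists passed by edgeR, and 1 of 26 passed in the MYC list. This was Odc1, the first enzyme of polyamine synthesis (log2 fold change 0.45, SE 0.11), which lies within 20 Mb of Pik3cg and stood at -0.54 in T-like cells. Without KO1 the MYC, glycolysis and nuclear oxidative phosphorylation lists had no call.

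A few markers of other B cell states were higher in follicular B-like cells. The germinal centre list had a call as higher (6 of 8 members, camera adjusted p = 0.0326; adjusted p = 0.430 with an estimated correlation). Of the 8, Basp1, a membrane-associated signalling protein, alone passed when adjusted over the list alone (log2 fold change 0.95, SE 0.24). The memory B list had a call as higher (4 of 7 members, camera adjusted p = 0.0279; adjusted p = 0.430 with an estimated correlation) through Parm1 and S100a6, which both passed when adjusted over the list alone. Its median log2 fold change was 0.03. The interferon-stimulated list was higher (all 24 members, median 0.90, camera adjusted p = 9.92e-05; adjusted p = 0.576 with an estimated correlation). It had 0 members past the threshold by edgeR when adjusted over the list alone. Without KO1 its median was -0.45. In KO1, clusters led by interferon-stimulated genes held 24.97% of cells, against 1.07% to 5.32% in the other 5 mice. The 15 lists without a call included B cell identity (camera adjusted p = 0.0536), NF-kB and survival (0.113), cholesterol synthesis (0.147), migration receptors (0.760) and other class I PI3K subunits and phosphatases (0.433). The PI3K list, the unfolded protein response, B cell receptor activation and T cell activation had a median, mean and test that differed in sign.

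In T-like cells, 21 of 8304 genes passed, 10 higher and 11 lower in KO (edgeR; 15 by DESeq2). Higher genes included Ccl5, a chemokine of effector T cells (53.5 ± 14.8 to 184 ± 129 CPM, SD, n = 3 each; log2 fold change 1.71, SE 0.32, edgeR adjusted p = 0.0195) and Igf1r, the receptor of insulin-like growth factor (log2 fold change 1.02, SE 0.15, edgeR adjusted p = 0.00239). Others were Pde2a, a cyclic nucleotide phosphodiesterase (ENSMUSG00000110195, chromosome 7, 101421691 to 101512827; 42.6 ± 4.41 to 84.8 ± 1.21 CPM, log2 fold change 0.98, SE 0.13, edgeR adjusted p = 0.000587), and the integrin chain Itga4 (0.49, SE 0.10, edgeR adjusted p = 0.0303). For Ccl5, KO1 held 330 CPM against 87.0 and 135 CPM in KO2 and KO3. Without KO1 its log2 fold change was 0.97 (adjusted p = 0.000546, range over its alternatives 3.75e-41 to 0.597). Plac8, Hdgfl3, BE692007 and Sidt1 rose by log2 fold changes of 1.08, 0.77, 0.55 and 0.52. Rnf144a fell from 28.1 ± 1.89 to 5.63 ± 2.87 CPM (log2 fold change -2.34, SE 0.29, edgeR adjusted p = 0.000501). Heat-shock genes fell: Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) from 189 ± 20.3 to 66.3 ± 23.4 CPM (log2 fold change -1.47, SE 0.16, edgeR adjusted p = 0.000130). Hspa1a fell by a log2 fold change of -1.61, Dnajb1 of -0.76 and Hsph1 of -0.68. Also lower were Ccr9, a gut-homing chemokine receptor (log2 fold change -1.13, SE 0.21, edgeR adjusted p = 0.0174), and Id3, an inhibitor of E proteins (-0.70, SE 0.10, edgeR adjusted p = 0.00239). So were Rgcc (-0.93), the AP-1 gene Jun (-0.78) and the stress-induced phosphatase subunit Ppp1r15a (-0.91). Gm8369, Gm11290 and Rnf157 were called as well and were chosen after their values were seen. The T-like class pools several clusters. For all these genes, a changed mix of T cells and a changed expression within cells were not told apart. Cluster 11, an unnamed cluster led by Ccl5, lies outside the class. It made up 1.99% of WT and 2.14% of KO cells, while the T-like share was 24.8% and 12.6%. The count was 11 without WT1, 6 without WT2 or WT3, 36 without KO1, 13 with lane 2 alone, 38 without the clusters led by interferon-stimulated genes and 108 without the filter on low counts.

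Of 27 lists tested in T-like cells, 7 were higher and 1 was lower in KO by camera. With an estimated correlation or with fry 0 kept a call, against 12 lists at an unadjusted camera p under 0.05. The dissociation and stress list was lower (15 of 17 members, median -0.41, camera adjusted p = 1.23e-26; adjusted p = 0.221 with an estimated correlation). Of its members, 9 passed when adjusted over the list alone. The regulatory T list was higher (all 5 members, camera adjusted p = 0.00127; adjusted p = 0.453 with an estimated correlation). Its members included Il2ra, the high-affinity chain of the interleukin 2 receptor (log2 fold change 0.53, SE 0.17), and Ikzf2, the transcription factor Helios (0.44, SE 0.14), which passed when adjusted over the list alone. Foxp3 stood at 0.21 (SE 0.18). The T-like class includes cluster 12, whose leading genes include Ikzf2, Il2ra and Foxp3. It held 56, 78 and 67 of the 607, 955 and 816 T-like cells in the WT mice. In the KO mice it held 35, 51 and 30 of 333, 500 and 333. A changed share of that cluster and a changed expression within cells were not told apart. The antibody-secreting cell list was higher (camera adjusted p = 0.00127; adjusted p = 0.269 with an estimated correlation) through Ly6c2, Ly6a, Mzb1 and Tent5c. Of these, Ly6c2 and Ly6a are also expressed by activated T cells. Lists of genes of B cells had a call as higher in T-like cells as well. These were MHC class II presentation (all 7 members, 4 adjusted over the list alone, camera adjusted p = 2.25e-07; adjusted p = 0.329 with an estimated correlation), immunoglobulin constant genes (6 of 7, 3 adjusted over the list alone, camera adjusted p = 0.000111; adjusted p = 0.560 with an estimated correlation) and B cell identity (7 of 8, 0 adjusted over the list alone by edgeR, camera adjusted p = 0.0499; adjusted p = 0.560 with an estimated correlation). Without KO1 the latter 2 lists had no call, and KO1 held Igkc at 143 CPM against 35.6 and 51.7 CPM in KO2 and KO3. Ribosomal protein genes (75 of 87 higher, median 0.04, camera adjusted p = 0.000175) and interferon-stimulated genes (all 21 higher, median 0.54, camera adjusted p = 5.18e-05) also had a call (adjusted p = 0.675 with an estimated correlation for each), and without KO1 the interferon median was -0.33. The 19 lists without a call included T cell activation (camera adjusted p = 0.537), migration receptors (0.244), FOXO targets (0.170), mTORC1 and ATF4 targets (0.0841) and glycolysis (0.705). MYC targets and dark zone genes had a median, mean and test that differed in sign.

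The heat-shock members of the dissociation and stress list, a grouping made after seeing the data, were set side by side across classes. Hspa1a, Hspa1b, Hspa8, Hsph1 and Dnajb1 encode chaperones and co-chaperones of the heat-shock protein families. Adjusted over the list alone, 4 of the 5 were lower in KO in germinal centre B-like cells (median log2 fold change -0.58), all 5 in follicular B-like cells (median -0.80) and 4 in T-like cells (median -0.76). In cluster 9, 0 of the 5 passed by edgeR when adjusted over the list alone (median -0.01), and Hspa1b stood at a log2 fold change of -0.81 (SE 0.38) and Hspa1a at 0.22 (SE 0.44). Some immediate-early members of the same list were higher in KO. Adjusted over the list alone, these were Fos, Fosb, Egr1 and Jun in germinal centre B-like cells, Fos, Egr1 and Fosb in follicular B-like cells and Fos in cluster 9. Btg2 and Nfkbia were lower in follicular B-like cells, in which the 12 members outside the heat-shock genes had a median of -0.08. In T-like cells 0 members of the list were higher by edgeR when adjusted over the list alone, and 5 others besides the heat-shock genes were lower, among them Jun, Fos (log2 fold change -0.55, SE 0.14) and Btg2 (-0.41, SE 0.09).

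**Figure D3:**
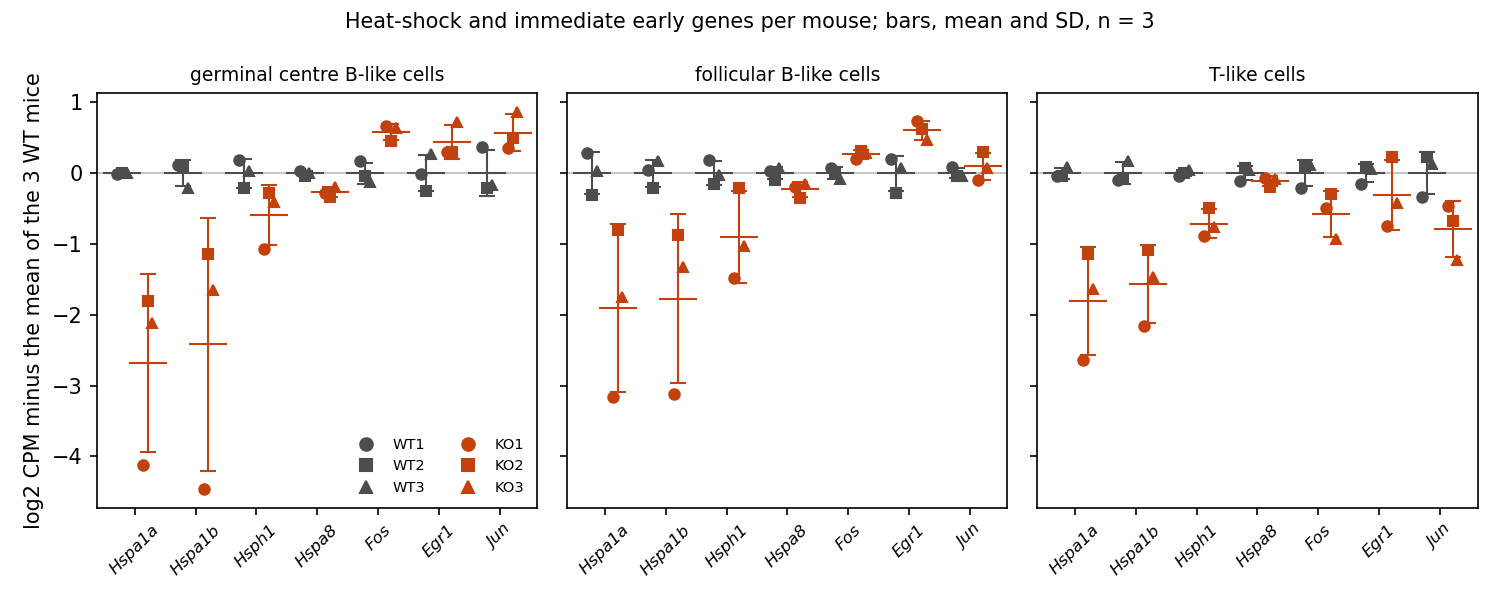
Log2 CPM, relative to the mean of the WT mice, of 4 heat-shock genes and of Fos, Egr1 and Jun per mouse (points) in germinal centre B-like, follicular B-like and T-like cells of WT and KO mice. Hspa1b in T-like cells averaged 189 CPM in WT and 66.3 CPM in KO mice.

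Cluster 9, 504 B-lineage cells that no marker list named, was added after seeing the clusters. Its leading genes included Fcrl5, Apoe, S100a6, Plac8 and Bhlhe41, as well as haemoglobin genes. It made up 2.52% ± 0.184 of B-lineage cells in WT and 4.22% ± 1.41 in KO mice (SD, n = 3 each), without overlap (exact permutation p = 0.1, Benjamini-Hochberg p = 0.275; chance share 10%). The KO mice had 3.50%, 5.85% and 3.31%, and without KO2 the difference was 0.887 points instead of 1.70. Within it, 3 of 2654 genes passed (edgeR; 1 by DESeq2). S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181), a calcium-binding protein and a member of the memory B list, rose from 356 ± 15.7 to 1069 ± 424 CPM (log2 fold change 1.58, SE 0.22, edgeR adjusted p = 0.00149). Nfatc1, a transcription factor of antigen receptor signalling, fell from 407 ± 58.4 to 205 ± 39.6 CPM (log2 fold change -1.03, SE 0.17, edgeR adjusted p = 0.0131). The third was the V segment Igkv12-46, chosen after its values were seen. The next genes by p had no call: Cdk8 (log2 fold change -0.47, edgeR adjusted p = 0.365), Bach2, a repressor of plasma cell differentiation (0.52, edgeR adjusted p = 0.458), Fos (0.69, edgeR adjusted p = 0.673) and Traf3ip3 (-0.96, edgeR adjusted p = 0.743). Of 22 lists, that of memory B genes was higher (camera adjusted p = 0.000284; adjusted p = 0.357 with an estimated correlation) through S100a6. The fry test called a different list as lower, the antibody-secreting cell programme (5 of 8 members lower, fry adjusted p = 0.00396; adjusted p = 0.411 with an estimated correlation). The other 21 lists had no call by camera, and FOXO targets, the unfolded protein response, G2 and M phase, and dissociation and stress had a median, mean and test that differed in sign. The gene count was 6 without WT1, 5 without WT2 or WT3, 1 without KO2, 34 without the filter on low counts, and 0 by edgeR with lane 2 alone (58 genes at an unadjusted p under 0.05).

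Receptor contigs gave the heavy-chain isotype of 2706 retained cells and a light chain of 10599. A heavy chain was recovered in 15.7% of germinal centre B-like, 19.5% of follicular B-like, 82.4% of antibody-secreting cell-like and 26.6% of cluster 9 cells. Among germinal centre B-like cells with a heavy chain, 94.0% ± 1.88 were class-switched in WT and 88.2% ± 3.74 in KO mice (SD, n = 3 each; exact permutation p = 0.1, Benjamini-Hochberg p = 0.483 over 29 receptor shares). IgG1 made up 76.2% ± 32.0 of the switched germinal centre cells in WT and 77.9% ± 8.71 in KO mice (exact permutation p = 1.0), and WT1 stood apart with 43.4% of its germinal centre cells on IgG2c. IGHV1-72, the V gene typical of the anti-NP response of C57BL/6 mice, was used by 23.9% ± 5.35 of WT and 16.4% ± 5.68 of KO germinal centre B-like cells (exact permutation p = 0.1, Benjamini-Hochberg p = 0.483; 20 cells in WT2), and lambda light chains by 30.9% ± 12.7 and 23.7% ± 1.02 (exact permutation p = 0.4). Over all cells with a heavy chain, 17.0% ± 14.0 were switched in WT and 33.6% ± 11.5 in KO mice (exact permutation p = 0.2), and in cluster 9 18.3% ± 9.96 and 33.9% ± 8.71 (exact permutation p = 0.1, 14 to 49 cells per mouse). The share over all cells depends on how many germinal centre B-like cells a mouse held. These were 26.9%, 4.61% and 8.06% of cells in WT1, WT2 and WT3 and 19.9%, 35.9% and 34.7% in KO1, KO2 and KO3.

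Among follicular B-like cells with a heavy chain, 0.487% ± 0.422 were switched in WT and 3.13% ± 0.444 in KO mice (SD, n = 3 each; exact permutation p = 0.1, Benjamini-Hochberg p = 0.483). Pooled over mice these were 5 of 999 and 27 of 840 cells, and IgG1 was found in 0 of 999 WT cells, which allows a share of up to 0.3003%, and in 13 of 840 KO cells. As shares of all follicular B-like cells, switched chains came to 0.0975% in WT and 0.620% in KO mice at medians of 1723 and 1806 UMIs per cell, and any heavy chain was found in 8 of 3544 T-like cells (0.23%), which should lack it, at a median of 2473.5 UMIs. The antibody-secreting cell-like cells had a heavy chain in 21 WT and 21 KO cells, of which 16 and 15 were IgG1. Of 42 antibody-secreting cell-like cells with 1 heavy chain, 7 shared a clone with germinal centre B-like cells, against 1 of 1841 follicular B-like and 0 of 133 cluster 9 cells (which allows up to 2.26%). Cells in clones of 2 or more made up 5.33% ± 6.13 of WT and 10.3% ± 5.21 of KO cells at equal cell numbers (exact permutation p = 0.2), and 10.4% ± 11.2 and 10.3% ± 0.772 of germinal centre B-like cells (exact permutation p = 1.0). The clone share over all cells also depends on how many germinal centre B-like cells a mouse held. For germinal centre B-like cells 20 cells were drawn per mouse, the number in WT2, which stood at 0%. Without WT2, at 50 cells, WT1 and WT3 had 30.9% and 24.0%. KO1, KO2 and KO3 then had 19.4%, 19.9% and 16.6% (exact permutation p = 0.1 over 10 assignments). Without WT1, at 20 cells, the means were 4.46% in WT and 10.3% in KO mice (exact permutation p = 0.1).

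V segments of germinal centre B-like cells differed from the germline reference at 3.70%, 3.33% and 2.98% of nucleotides in WT1, WT2 and WT3 and at 1.74%, 2.73% and 2.23% in KO1, KO2 and KO3. The means were 3.34% ± 0.363 and 2.23% ± 0.494 (SD, n = 3 each). Such differences arise by somatic hypermutation, in which germinal centre B cells mutate their receptor genes. The mice did not overlap (chance share 10%; exact permutation p = 0.1, Benjamini-Hochberg p = 0.160 over 8 tests, a measure added after seeing the data). Among switched germinal centre cells alone the means were 3.41% ± 0.415 and 2.39% ± 0.457 (exact permutation p = 0.1), and the mice overlapped with contigs of at least 3 UMIs or without IGHV1-72 (exact permutation p = 0.2 for each). Germinal centre B-like cells with at least 1% difference made up 89.4% ± 3.14 in WT and 77.2% ± 9.29 in KO mice, with overlap (exact permutation p = 0.2, Benjamini-Hochberg p = 0.267). Among switched cells alone these shares were 91.2% and 82.0% (exact permutation p = 0.1). In cluster 9 the order of the mean difference was the opposite, 0.217% ± 0.0528 in WT and 0.850% ± 0.142 in KO mice, without overlap (exact permutation p = 0.1, 14 to 48 cells per mouse). The mice of cluster 9 overlapped with lane 1 alone (exact permutation p = 0.4) and with contigs of at least 3 UMIs (exact permutation p = 0.3). Follicular B-like cells with IgM or IgD differed from the reference at 0.00470% ± 0.00410 of nucleotides in WT and 0.00730% ± 0.00330 in KO mice (exact permutation p = 0.5).

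**Figure D4:**
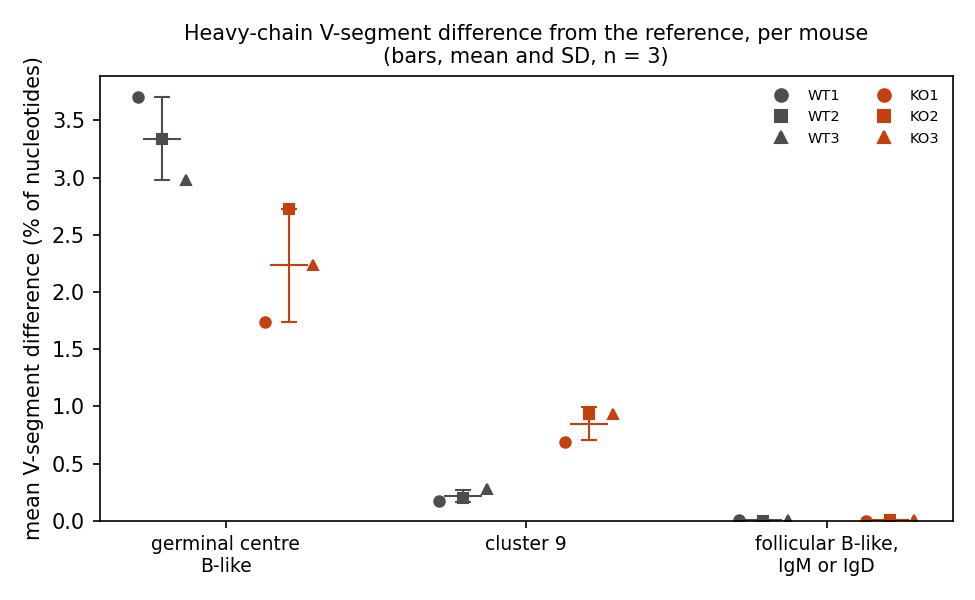
Mean difference of heavy-chain V segments from the germline reference, in percent of nucleotides, per mouse (points) for germinal centre B-like cells, cluster 9 and follicular B-like cells with IgM or IgD. Germinal centre B-like cells ran from 2.98% to 3.70% in WT and from 1.74% to 2.73% in KO mice.

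Whether the genotype effect differed between classes was tested as an interaction. Between germinal centre and follicular B-like cells it differed for 8 of 10679 genes (edgeR), among them Ighg1 (difference of log2 fold changes -1.39, SE 0.19, edgeR adjusted p = 0.00507) and Parm1 (-2.67, SE 0.38, edgeR adjusted p = 0.00507). Their log2 fold changes were 0.11 and 0.21 in germinal centre B-like cells against 1.52 and 2.92 in follicular B-like cells. The light-chain V segments Igkv2-137, Igkv12-98, Igkv6-17 and Igkv5-43, chosen after their values were seen, are also among the 8 genes. Between T-like and follicular B-like cells it differed for 32 genes. These include the V segments Igkv8-24, with the smallest p, Igkv1-117, Ighv1-80, Igkv6-15, Igkv12-46 and Igkv17-121, chosen after their values were seen. Pde2a (difference 1.38, SE 0.19, edgeR adjusted p = 1.03e-07), Itga4 (0.62) and Ccl5 (1.14) were more positive in T-like cells, and Jun (-0.91, SE 0.13, edgeR adjusted p = 3.03e-07), Rnf144a (-1.76), Ppp1r15a (-0.69) and Id3 (-0.53) more negative. The first count was 20 without KO3, and the other was 15 without WT2 and 57 without KO2.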

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

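In this part the tests of single mice, heat-shock genes, windows on other chromosomes and the cell mixture were chosen only after the results were seen, as was the choice of classes for the interaction.

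The genotype effect differed between cell classes by an interaction test with the mouse as a block. It did so for 8 genes between germinal centre and follicular B-like cells, among them Ighg1 (difference of log2 fold changes -1.39) and Parm1 (-2.67), both already high in germinal centre B-like cells of WT mice. It did so for 32 genes between T-like and follicular B-like cells, among them Pde2a (1.38), Ccl5 (1.14), Itga4 (0.62), Rnf144a (-1.76), Jun (-0.91), Ppp1r15a (-0.69) and Id3 (-0.53). These 32 genes also include Igkc, Cd74, H2-Aa, H2-Ab1 and H2-Eb1, B cell transcripts chosen after their values were seen and highest in KO1 for Igkc (143 CPM in T-like cells). Both counts include receptor V segments, which hold the smallest p in each: Igkv2-137 among the 8 and Igkv8-24 among the 32. The 10 ways to split the 6 mice into groups of 3 are too few for a share under 0.05: 1 split, the real one, gave as many genes in each case, with at most 6 and 23 genes in another split.

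Pik3cg RNA remained in the KO mice, and genes around it differed by genotype. The tables argue against a wrongly labelled mouse, since 0 of the 6 mice lay on the side of the other genotype for a signature of the genes near Pik3cg built without that mouse. A candidate explanation for the neighbouring genes is a linked stretch of another strain's chromosome around the targeted locus, which needs a higher share of differing genes there: the odds ratio was 4.27 in follicular B-like cells, and in these cells 0 of 118 other windows of 40 Mb had a share as high, the next being 17.5% on chromosome 16. Nova1, Rnf144a and Asap2 may then differ through their own alleles rather than through loss of PI3K gamma. An effect of PI3K gamma on these genes stays open and was not tested.

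Heat-shock RNA was lower in the KO mice in germinal centre B-like, follicular B-like and T-like cells, while 0 of the 5 genes passed in cluster 9. The heat-shock genes themselves are not linked to Pik3cg, since by genome position 0 of the 5 lie within 20 Mb of it. Whether the differing genes near Pik3cg act on them was not tested. In germinal centre and follicular B-like cells, not every member of the dissociation and stress list was lower. There 4 members (Fos, Fosb, Egr1 and Jun) and 3 members (Fos, Egr1 and Fosb) were higher in KO when adjusted over the list alone. The limit of 3 was set after seeing the results, so it could not fail and does not test handling. In follicular B-like cells 7 members were lower when adjusted over the list alone, and the list had a call as lower (median -0.17, camera adjusted p = 5.16e-05). In T-like cells 0 members were higher. A handling response limited to the heat-shock genes was not tested in any class. Handling and genotype cannot be told apart in any of the classes, because the time and temperature each mouse's cells passed through are not recorded. An effect of the genotype itself stays open and was not tested.

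The share of T-like cells was lower in the KO mice. Another ratio of enriched to untouched cells would by itself lower all cells outside the B lineage alike, and so would a larger B cell compartment in the node. The mean share of the other cells outside the B lineage was 0.620 times that of WT (exact permutation p = 0.1), beside 0.561 times for T-like cells with the unnamed clusters that carry Cd3e, but those clusters, 11 and 14, taken alone were not lowered alike, at 1.08 and 0.888 times (exact permutation p = 0.7 and 0.6). Among cells outside the B lineage, these T cells made up 85.7% ± 3.95 in WT and 85.0% ± 1.86 in KO mice (exact permutation p = 0.7), while T-like cells alone made up 76.5% ± 4.71 and 68.7% ± 2.26 without overlap (exact permutation p = 0.1). Plasmacytoid dendritic cell-like cells stood at 0.861 times and the unnamed cluster 23 at 1.24 times (exact permutation p = 0.6 and 0.4). NK-like, dendritic cell-like and macrophage or monocyte-like cells were lowered, at 0.579, 0.584 and 0.437 times (exact permutation p = 0.1 for each). For clusters 11 and 14 the values argue against a mixing ratio alone, or a larger B cell compartment alone. Whether mixing lowered part of the T-like share, beside a biological change, cannot be told, because the mixing of each mouse is not recorded.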

How the results depend on the processing

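The alternatives without the clusters led by interferon-stimulated genes or without damaged-looking clusters, and all those of cluster 9, of the interactions, of the V-segment difference and of the genes near Pik3cg, were chosen after the results were seen. No paired analysis was possible because the mouse numbers are only names: the hashtags give no animal, litter or day shared by a WT and a KO mouse, and both lanes hold all 6 mice. RLE size factors and a mitochondrial limit of 5% kept every call among the 30 named gene results past the threshold. DESeq2 kept 21 of 30, resolution 2 kept 21 of 28, Scrublet calls kept 23 of 27, lane 1 alone 14 of 29 and lane 2 alone 11 of 28. Leaving out WT1, WT2 or WT3 kept 12, 12 and 11 of 30, against 27, 23 and 19 without KO1, KO2 or KO3. None of these calls changed direction. The cause of each change was not tested, except that lanes and left-out mice give fewer cells or samples. Scrublet calls kept and resolution 2 also changed the clusters and so the cells of a class (753 and 1256 follicular B-like cells in WT1, against 1415). V-segment differences kept their direction in all 24 alternatives with 1 mouse left out and in 19 of 20 others, receptor shares in all 23 that left out no mouse.

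The number of genes past the threshold moved by over 1.5 times as follows. Without a filter on low counts it was 167 in germinal centre B-like, 186 in follicular B-like and 108 in T-like cells and 34 in cluster 9. With lane 1 alone it was 5 in germinal centre B-like cells, and with lane 2 alone 4, 1, 13 and 0 in the same order (58 genes at an unadjusted p under 0.05 by edgeR in cluster 9, where DESeq2 on both lanes called 1). In germinal centre B-like cells, immunoglobulin genes left out gave 19. Scrublet calls kept 1 and resolution 2 gave 2 in follicular B-like cells. Lane 1 alone gave 7 there, sharing 1 with the main 6. Without interferon-led clusters there were 18 in follicular B-like and 38 in T-like cells, which included all 6 and 21 of the main calls. With 1 mouse left out the range was 3 (WT1) to 17 (KO1 or KO3) in germinal centre B-like, 0 (WT1, WT2 or KO3; edgeR, 554 to 699 genes at an unadjusted p under 0.05) to 23 (KO1) in follicular B-like cells. It was 6 (WT2 or WT3) to 36 (KO1) in T-like cells and 1 (KO2) to 6 (WT1) in cluster 9. For the interactions it was 7 to 20 (KO3) and 15 (WT2) to 57 (KO2).

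Lists past the threshold fell to 0 in all 4 classes with an estimated correlation and to 0 with fry in germinal centre B-like, follicular B-like and T-like cells. Lane 2 alone gave 7 in follicular B-like and 4 in T-like cells, and each lane gave 2 in cluster 9. With 1 mouse left out they ranged from 1 to 5 in germinal centre B-like cells, 6 to 11 in follicular B-like cells and 1 to 3 in cluster 9. The interferon list reversed without KO1: its median ran from -0.12 to 0.71, from -0.45 to 1.38 and from -0.33 to 0.95 in germinal centre B-like, follicular B-like and T-like cells.

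These directions reversed. The log2 fold change of Pik3cg was 0.06 (0.0566) in germinal centre B-like cells with lane 2 alone and ran from -0.20 to 0.41 in T-like cells with 1 mouse left out. The difference in the antibody-secreting share of all cells was 0.0071 points with Scrublet calls kept, 0.01 on the log2 scale by edgeR (0.006), and -0.129 to 0.0739 points with 1 mouse left out. Of B-lineage cells it was -0.217 to 0.0306 points. IgG1 among switched germinal centre cells ran from -16.6 to 13.5 points, and clonal expansion in germinal centre B-like cells was 0.34 points with amino acid CDR3s, 10.1 points with all cells and -8.80 (without WT2) to 5.81 (without WT1) points with 1 mouse left out. The V-segment difference of follicular B-like cells with IgM or IgD was -0.0051 points with contigs of at least 3 UMIs. The odds ratio near Pik3cg was 0.572 in T-like cells with lane 1 alone. The T-like share passed the threshold by edgeR on cell numbers (log2 fold change -0.98).

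Comparisons of antibody-secreting and memory B-like cells, their interactions and the replicate block were not run, for lack of cells, of a cluster and of a pairing; some lane and contig alternatives of receptor shares had under 10 cells in a mouse and gave no value. At this depth simulated 2-fold changes were recovered in 74.2% of cases in germinal centre B-like and 85% in follicular B-like cells, and recovery by level of expression was not tested. The simulated counts held no gene-specific spread and no outlying mouse, so recovery in the real mice can differ.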

Other observations

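In this part the interferon-led clusters, the small cell classes and the residues of IGHV1-72 were looked at only after the data were seen.

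Several classes outside the B and T lineages had lower shares in each KO mouse than in each WT mouse. NK-like cells made up 1.25% ± 0.498 of WT and 0.721% ± 0.105 of KO cells (SD, n = 3 each), dendritic cell-like cells 1.77% ± 0.196 and 1.03% ± 0.453, and macrophage or monocyte-like cells 0.758% ± 0.168 and 0.331% ± 0.114, each without overlap between the genotypes (two-sided exact permutation p = 0.1 for each, the smallest possible; chance share 10%). Plasmacytoid dendritic cell-like cells were 0.413% ± 0.195 and 0.355% ± 0.139 (exact permutation p = 0.6). The mixing of each mouse is not recorded.

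KO1 stood apart in interferon-stimulated genes, which cells switch on after type I or III interferon. The follicular B-like and T-like clusters led by such genes held 696 of its cells (24.97%), against 104, 157 and 178 cells in WT1, WT2 and WT3 and 43 and 72 in KO2 and KO3. No label tells what set this mouse apart. In receptors that use IGHV1-72, counted from 1 at the first residue of framework 1, the most frequent change among positions 26 to 32 of the first complementarity-determining region was S31N, in 14 of 74 WT and 17 of 111 KO cells. S31V was found in 11 of 37 such cells of KO3 and in no such cell of the other mice. Whether these 11 cells are 1 clone was not tested. Positions after 32 were not examined.

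How often other groupings of the mice give results as large was counted over the 10 splits of the 6 mice into groups of 3, which are too few for a share under 0.05. For genes past the threshold, the real split gave 11, 6, 21 and 3 in germinal centre B-like, follicular B-like and T-like cells and cluster 9, and the highest of the other splits gave 4, 1, 2 and 2, so that 1 split reached the real count in each. For lists past the threshold, the real split gave 3, 11, 8 and 1, and the highest of the other splits gave 8, 6, 13 and 2: 6, 1, 3 and 9 of the 10 splits reached the real number.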
